A study of Mus musculus with 203 samples.

How the data were processed

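RNA of 63 types of mouse cell or tissue was hybridised to single-colour Illumina bead arrays, 203 arrays in all. Per the labels, cells of C57BL/6 mice were sorted by surface antibodies, total RNA was isolated and checked for integrity, and it was amplified with a kit and labelled with biotin. Per the file headers, one deposited table holds the average bead signal intensity of each probe with no normalization, beside a detection score. The deposited score is headed a detection p-value, but it rises with the intensity to 1, so it was read as 1 minus a p-value, except for 14 control probes whose scale runs the other way (Spearman correlation with signal −0.913) and was turned. The other deposited table holds log2 values that the authors normalized between arrays by a method the files do not name. All computing below started from the intensities, and the deposited log2 values served as an alternative.

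Background correction and quantile normalization were done with neqc of limma 3.58.1 in R 4.3.3 (normexp from the detection values, offset 16, log2). The result differed from the deposited log2 values by a median of 0.02 and at most 0.10. A probe was kept when its detection score was at least 0.99 on at least 2 arrays. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none; only the first kind was named. Symbols of 34807 probes were found through their gene ID in a RefSeq table of the assembly GRCm38.p6, used for names only, since the files name no genome build. The brightest probe by mean over all arrays stood for a gene, which left 15913 genes, 7190 of them with over 1 probe. In some of these the probes disagreed in direction, as is said for Csf2rb, Rpl4, Atg4d, Hspa1b, Steap3, Sptb and Foxp3; a probe differed at least 2-fold the other way for 218 of the genes called in Baso, 201 in EryBlPO and 96 in Eo. A gene detected on no array of a group is described as not well above background there, and its fold is a lower bound, set against the higher of its own signal and the lowest signal among detected probes on each array. A gene detected on only some arrays of a group can have a mean there below that lowest signal, so its fold is approximate. Arrays detected between 5.50% and 48.8% of probes, and the number of arrays limits the precision of every value.

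Each cell type was a group in 1 linear model (140 residual degrees of freedom; lmFit, contrasts and eBayes with an intensity trend), so that all types share 1 estimate of the spread. p-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. A gene was called lineage-enriched when the mean over the types of its lineage passed both limits against each of the other 12 lineages. Gene lists were tested with camera at a preset correlation of 0.01 (105 tests, adjusted together), of which 62 passed, and 50 passed with an estimated correlation. The text names, per comparison, the 7 largest rises and 7 largest falls among called genes whose groups do not overlap (the overlap was not considered for the interaction and the blood contrast), up to 3 list members with the smallest adjusted p per list, list members beside their count, and, per lineage, the 4 genes with the largest margin and fixed markers; not every such gene is printed. The groups, tests, lists and rule were fixed before the data were examined.

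The files name no chips. A prefix shared by signal columns was taken as the run, giving 17 runs, called A to Q here. Run was fitted as a fixed block where the contrast stayed estimable (15 of 16 comparisons, 21 of 78 lineage contrasts), as a random block (correlation 0.28), and by fits that kept only 1 run for the groups compared and all arrays of the other types; a lone array left in a group is assumed to vary like the other groups. These alternatives were chosen after seeing the data, as were median scaling to the 974 probes detected on all arrays, no normalization between arrays, and leaving out the 17 arrays that detected under 25% of probes. The alternatives planned beforehand were the deposited log2 values, no background correction, no filter on dim probes, the mean of all probes of a gene, adjusted p alone, only the arrays compared, the replicate number as a block, the cell type as the replicate and no cultured sources for the blood contrast, every type above every other for lineages, and leaving out each array in turn. Same-numbered arrays deviated together in every pair only for cDC1 and cDC2 (correlation of deviations over genes at least 0.14 in each of 3 pairs, mean 0.26). This pairing was seen in the data alone, and the replicate block left all list calls of cDC1 and cDC2 in place. The mean was higher for PreB and ProB (0.41) and for TN3 and TN2 (0.27), but their lowest pairs were at −0.013 and −0.106.

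The fits were tested on simulated data. With 4-fold changes, limma recovered 90.9% of changed genes for cDC1 against cDC2, 95.5% for LTHSC against MPP, 77.3% for Baso against Mast and 95.5% for RegT against NveCD4T. With 2-fold changes it recovered 34.3%, 35.8%, 23.9% and 38.8%. False calls were 0, 3, 4 and 4 in the same order. The simulated noise was independent between genes and arrays, with the same spread in every group and no run effect. These shares and counts are therefore no error rates of the real comparisons, whose arrays also differ by run. The lineage rule recovered 94% of 4-fold genes for dendritic cells and 80% for NK cells.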

Results

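Gene expression was measured on single-colour Illumina arrays in RNA from 63 types of mouse cell or tissue, with 203 arrays in all. Of these, 178 arrays held 55 types of blood cell, placed by the labels in 13 lineages, and 25 arrays held 8 other sources: brain, kidney, liver, lung, ovary, testis, cultured embryonic stem cells and cultured embryonic fibroblasts. Each type had 2 to 9 arrays. An array detected between 5.50% and 48.8% of its probes. Levels below are normalized log2 intensities, given as mean ± SD over arrays, and those near the top of the scale are compressed by saturation. A gene was called when its limma adjusted p was under 0.05 and its change at least 2-fold, among 15913 genes tested. Where a gene was detected on only some arrays of a group, its level there can lie below the lowest detected signal and its fold is approximate. The labels do not say that the arrays of a type came from separate animals, so all p-values measure the spread between these samples. Gene lists were fixed before the data were examined and tested with camera. Their counts adjusted over the list alone equalled those over all genes except where both are given.

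The lineages were first compared with each other, to find genes that set each apart from the other 12. Mast cells had the most such genes, 504 (2 arrays), led by Tph1, the first enzyme of serotonin synthesis. Tph1 stood at 13.87 against 5.20 in the next lineage (log2 difference 8.68, SE 0.31). Its largest limma adjusted p against the other 12 lineages was 1.68e-47. Such p-values measure the spread between arrays of a type, not between types. The tryptase gene Tpsab1 came next (difference 8.44, SE 0.38). Neutrophils had 389 (5 arrays), among them the chitinase-like Chil1 (6.26, SE 0.45), and erythroid cells 320 (17 arrays), among them Tspan8 (5.51, SE 0.18) and the red cell membrane gene Ermap (5.41, SE 0.19). NK cells had 301 (2 arrays), led by the receptor gene Klra8 (6.35, SE 0.38), and megakaryocytes 247 (9 arrays), led by the platelet chemokine Ppbp (7.73, SE 0.33) and the platelet tubulin Tubb1 (7.60, SE 0.18). Basophils had 192 (2 arrays), led by the glutamate receptor Grm6 (6.73, SE 0.29), dendritic cells 117 (12 arrays), led by the transcription factor Mycl (4.79, SE 0.19), and multipotent progenitors 94 (26 arrays), led by the homeobox gene Nkx2-3 (3.43, SE 0.14). B cells had 90 (15 arrays), led by Chst3 (5.73, SE 0.24), with the transcriptional coactivator Pou2af1 (5.25, SE 0.28) among them, and macrophages and monocytes 76 (11 arrays), among them the scavenger receptor Msr1 (3.96, SE 0.21). Eosinophils had 46 (6 arrays), led by eosinophil peroxidase, Epx (5.73, SE 0.53), and T cells 39 (43 arrays), led by Trat1, an adaptor of the T cell receptor (4.93, SE 0.25). For restricted progenitors (8 types, 28 arrays) only Cdk6 (1.52, SE 0.29) and Gm2629 (1.02, SE 0.11) passed, by the mean over the types, and neither did when every type had to exceed every type outside (smallest differences −2.58 and −2.67). Markers listed beforehand passed for B cells (4 of 4 measured), megakaryocytes (5 of 5), NK cells (4 of 5), neutrophils (4 of 5), dendritic cells (4 of 6), T cells (3 of 4), mast cells (3 of 5), erythroid cells (2 of 4), basophils (2 of 5), macrophages (2 of 5) and eosinophils (2 of 6), but for neither multipotent (0 of 5) nor restricted progenitors (0 of 6). Counts rose to 325 for basophils without Baso-2 and 488 for NK cells without NK-2, and fell to 166 for erythroid cells without the arrays that detected under 25% of probes, which removed 3 of the 6 erythroid types (EryBlPO, EryBlPB and Retic) altogether. The counts and their order also depended on scaling. Without normalization between arrays mast cells had 1574, B cells 162, T cells 121, macrophages 117, erythroid cells 98, megakaryocytes 58, multipotent progenitors 51, NK cells 26 and basophils 17. With median scaling mast cells had 946, NK cells 190, erythroid cells 159, basophils 96, dendritic cells 67, multipotent progenitors 60 and restricted progenitors 1. Without background correction NK cells had 187, basophils 114, dendritic cells 77, macrophages 49, multipotent progenitors 39, T cells 24 and restricted progenitors 0. When every type of a lineage had to exceed every type outside it, 174 genes were left for mast cells, 13 for erythroid cells and 0 for dendritic cells and restricted progenitors.

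**Figure D1:**
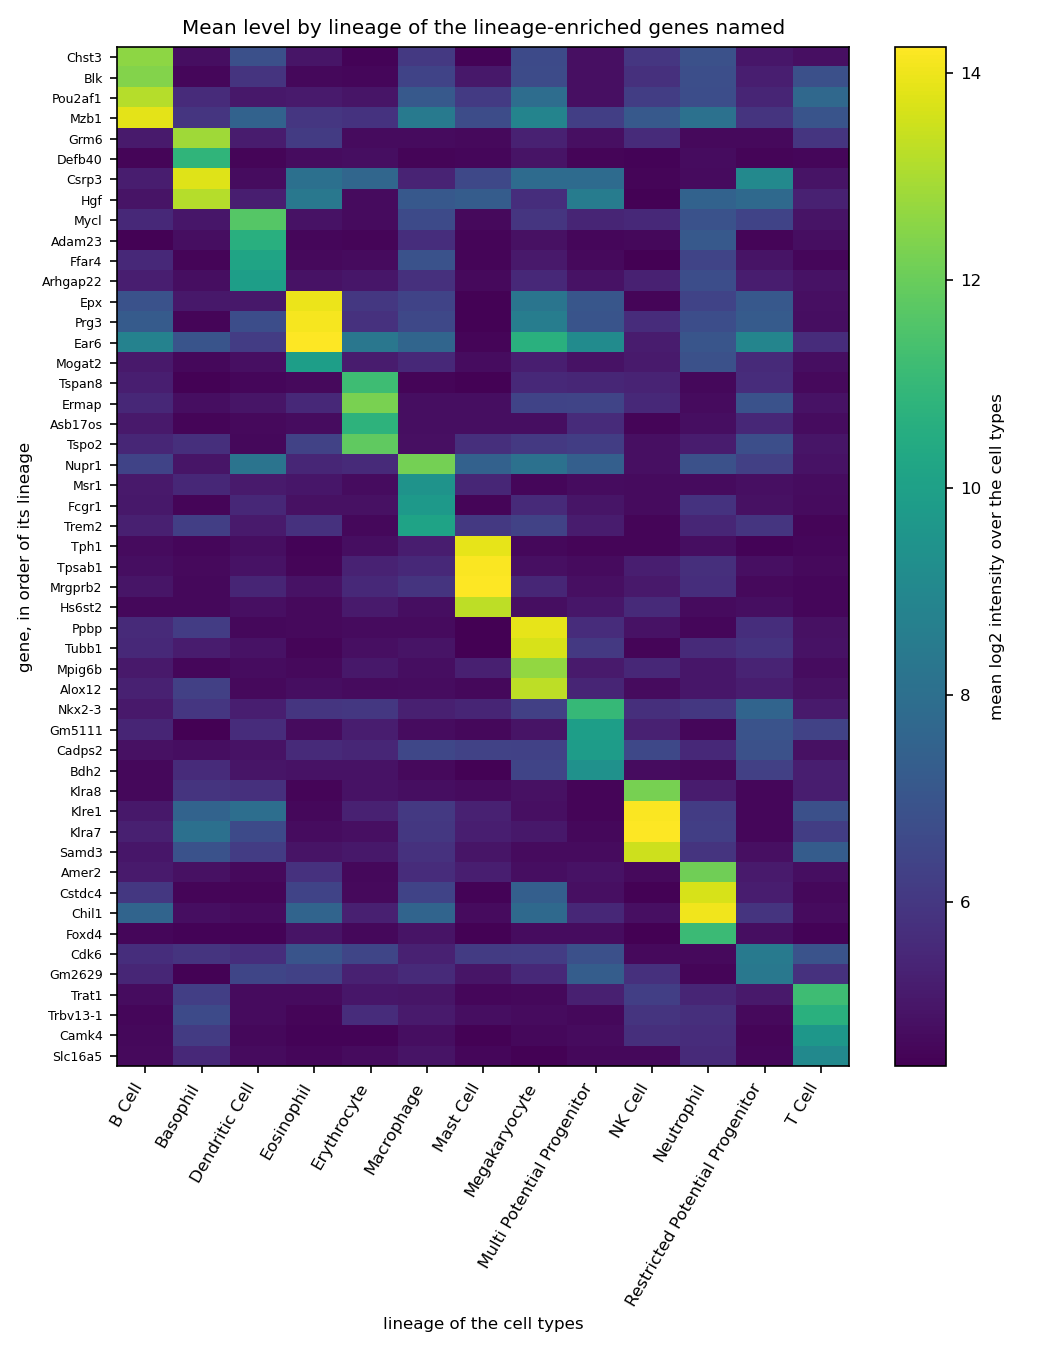
Mean log2 intensity of the lineage-enriched genes named by the rule (rows) in each of the 13 blood lineages (columns, each a mean over the cell types of that lineage), with brighter colour for a higher level. Each block of genes is brightest in its own lineage, for example Tph1 at 13.87 in mast cells against 5.20 in the next lineage.

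The 55 blood cell types (178 arrays) were then compared with the 8 other sources (25 arrays), each type weighing equally. The p-values of this contrast measure the spread between arrays of a type, not between types. By limma, 13296 of 15913 genes had an adjusted p under 0.05. Rac2, a small GTPase, was 60.7-fold higher in blood cells (log2 difference 5.92, SE 0.08, limma adjusted p = 3.26e-114), and the transcription factor Ikzf1 50.2-fold higher. Matrix genes were lower: Sparc by 130-fold and the collagen-binding proteoglycan Dcn by 67.8-fold, with Ccn2, a connective tissue growth factor, 159-fold lower. All 18 pan-leukocyte genes rose, with a median of 3.84 (camera adjusted p = 4.33e-16). Of 18 measured matrix genes 17 fell, with a median of −3.08 (1.75e-11). Epithelial genes fell in 9 of 10 (median −2.35, 1.49e-05), among them the claudin gene Cldn3 by 10.7-fold, and imprinted genes in 8 of 10 (median −3.02, 5.65e-06), among them Peg3 by 19.5-fold. Endothelial genes fell in 7 of 11 and rose in 1, Pecam1 (median −1.97, 0.00222; adjusted p = 0.0624 with an estimated correlation). In all, 4585 genes were called, 1862 higher and 2723 lower in blood cells, against 958 and 4756 with median scaling, 3127 and 1962 without normalization between arrays, and 2616 in all without background correction. This contrast could not be fitted with run as a fixed block.

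Long-term stem cells (LTHSC, n = 4) and multipotent progenitors (MPP, n = 6) of bone marrow were compared as the first step of blood formation. Vwf, a clotting protein of platelets and endothelium, was 40.1-fold higher in LTHSC (11.69 ± 0.38 against 6.37 ± 0.28; log2 difference 5.32, SE 0.35, adjusted p = 2.29e-29) and was detected on 5 of 6 MPP arrays. The transglutaminase gene Tgm2 was 39.3-fold higher (12.84 ± 0.27 against 7.54 ± 0.31). Emp1 was lower (5.63 ± 1.05 against 11.10 ± 0.24, detected on 2 of 4 LTHSC arrays), and Cox6a2, not well above background in LTHSC, at least 12.4-fold lower. Dntt, the polymerase that adds nucleotides during receptor gene assembly, was lower (5.21 ± 0.84 against 10.53 ± 0.94, detected on 1 of 4 LTHSC arrays). Of 17 measured stem cell regulators 12 rose, with a median of 2.28 (adjusted p = 7.81e-23), including the homeobox gene Hoxb5 by 15.8-fold. Lymphoid priming genes fell in 6 of 12, with a median of −0.93 (4.01e-10), including the chromatin organizer Satb1 by 6.94-fold and Flt3, which was used in sorting and is no finding. Cell cycle genes fell in 11 of 25 (median −0.95, 4.01e-10), among them the topoisomerase Top2a by 3.62-fold. Erythroid genes rose in 3 of 8 (median 1.46, 8.55e-06): Klf1, the erythroid transcription factor, by 13.7-fold, the erythropoietin receptor Epor by 9.86-fold and the carbonic anhydrase Car1 by 16.6-fold. Mast cell and basophil genes (3 of 9 lower, 4 adjusted over the list alone, median −0.82, adjusted p = 0.0828) and stress genes (1 of 14 higher, median 0.62, 0.258) did not pass as lists. In limma, 1409 genes were called, 818 higher and 591 lower, against 1193 and 343 with median scaling, 168 and 1467 without normalization between arrays, and 666 in all without background correction. With run as a block 1207 were called, with 1313 within run G (3 and 3 arrays) and 633 within run D (1 and 3 arrays).

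Eosinophil progenitors (EoP, n = 3) were set against granulocyte-macrophage progenitors (GMP, n = 7). Epx, eosinophil peroxidase, was 98.8-fold higher in EoP (13.92 ± 0.12 against 7.30 ± 0.66; log2 difference 6.63, SE 0.69, adjusted p = 6.11e-15) and detected on 6 of 7 GMP arrays. The granule protein gene Prg3 was 55.8-fold higher (14.29 ± 0.06 against 8.48 ± 0.35), and Crhbp, not well above background in GMP, at least 16.0-fold higher. Ly86, which partners a Toll-like receptor homologue, was 7.21-fold lower (8.92 ± 0.35 against 11.77 ± 0.44), and Clec5a and Ccr2, not well above background in EoP, were at least 3.04-fold and 1.72-fold lower. Eosinophil granule genes rose in 4 of 5 (5 adjusted over the list alone; median 5.90, adjusted p = 5.53e-12), and eosinophil receptors and enzymes in 4 of 8 (median 0.95, 2.64e-07), including the lipoxygenase Alox15, at least 4.94-fold, and Il5ra, which served in sorting. Monocyte and macrophage regulators fell in 9 of 10 (10 adjusted over the list alone; median −2.22, 7.16e-15), among them Irf8 by 6.01-fold. Mast cell and basophil genes rose in 5 of 9 (median 2.02, 0.000276; adjusted p = 0.0569 with an estimated correlation), among them Ms4a2, a chain of the IgE receptor, by 4.06-fold. Cell cycle genes fell in 2 of 25, Ccne2 and Tyms (median −0.43, 0.000182; adjusted p = 0.143 with an estimated correlation). The primary neutrophil granule list did not pass (1 of 6 higher, median −0.07, mean 0.28, camera adjusted p = 0.68). The 1 was Cebpe (6.13-fold), a transcription factor and no granule protein. The secondary list did not pass (2 of 11 lower, with 1 higher adjusted over the list alone, median −1.06, 0.0572). Its median was 1.43 with run as a block and within run H. That list also holds the receptor gene Cxcr2, 1 of the 2 lower, and S100a8 and S100a9, which encode no granule proteins. Erythroid genes (2 of 8 higher, median −0.01, mean 0.17, 0.481) did not pass. Nor did stress genes (3 of 14 higher and 2 lower, 5 and 3 adjusted over the list alone, median 0.95, 0.306). In limma, 1151 genes were called, 680 higher and 471 lower, against 98 and 266 without normalization between arrays and 495 in all without background correction. A run block gave 1004 calls, with 872 within run H (3 and 3 arrays), and the erythroid list then passed (median 0.78, camera adjusted p = 0.00252). With that block the median was 7.20 for eosinophil granule genes and 1.35 for mast cell and basophil genes.

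Mature eosinophils (Eo, n = 3) were compared with EoP (n = 3). Serpinb2, a serine protease inhibitor not well above background in EoP, was at least 26.5-fold higher in Eo (11.30 ± 0.30; adjusted p = 6.33e-62). Mmp9, a gelatinase of neutrophil granules, was 89.9-fold higher (12.97 ± 0.37 against 6.48 ± 0.66, detected on 1 of 3 EoP arrays), and lactoferrin, Ltf, 70.1-fold higher (14.03 ± 0.39 against 7.90 ± 0.61; log2 difference 6.13, SE 0.94, adjusted p = 2.72e-08). Crhbp, not well above background in Eo, was at least 16.3-fold lower and the vesicle protein gene Plvap at least 6.53-fold lower. All 11 measured genes of the secondary neutrophil granule list rose (median 4.87, camera adjusted p = 1.13e-14). Eosinophil receptors and enzymes rose in 5 of 8 and fell in 1, Csf2rb (median 1.83, 5.49e-07). The fall of Csf2rb was seen on its brightest probe alone (−1.12), while its 2 other probes rose by 0.69 and 1.10. Alox15 rose by 30.3-fold and the eotaxin receptor Ccr3 by at least 18.9-fold, while the sorting marker Siglecf varied between Eo arrays (7.24 ± 2.69) and was not called without Eo-1. Eosinophil granule genes (0 of 5; median 0.09, adjusted p = 0.68, with a median of −1.03 under median scaling and −0.735 with run as a block) did not pass, nor did primary neutrophil granule genes (0 of 6; median −0.64, 0.67), mast cell and basophil genes (3 of 9 lower; median −0.79, 0.124, but 0.32 with run as a block) or stress genes (3 of 14 higher, 4 adjusted over the list alone, and 1 lower; median −0.20, mean 0.04, 0.407). Ribosomal protein genes (1 of 19 higher, 3 lower, Rpl4 on only 1 of its 2 probes; median −0.27, 0.155) passed only with run as a block (adjusted p = 0.0171). In limma, 3428 genes were called, 1409 higher and 2019 lower, against 1661 and 1148 with median scaling, 4199 and 30 without normalization between arrays, and 2082 in all without background correction. No run held both types; with run as a block, resting on the other types, 1342 genes were called, 716 higher and 626 lower.

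Polychromatic erythroblasts (EryBlPO, n = 3) were compared with the earlier erythroid colony-forming cells (CFUE, n = 3) to follow red cell maturation. Kcnc4, Fn3k and Tmod1, not well above background in CFUE, were at least 120-fold, 116-fold and 76.0-fold higher. Tmod1, which caps actin filaments of the red cell membrane, reached 12.40 ± 0.25. The mitochondrial iron importer gene Slc25a37 was 32.3-fold higher (14.40 ± 0.13 against 9.39 ± 0.07; log2 difference 5.01, SE 0.35, adjusted p = 5.52e-28). Kit, the stem cell factor receptor, and Srm, spermidine synthase, were not well above background in EryBlPO and at least 19.7-fold and 20.1-fold lower. Haem and iron genes rose in 9 of 13 (median 1.44, adjusted p = 4.72e-06), among them ferrochelatase, Fech, by 22.1-fold, and Steap3, which rose on 3 of its 4 probes and fell on the other (−2.60). Autophagy genes rose in 7 of 10 and fell in Atg4d and Atg7 (median 2.20, 0.00124), with Ulk1 11.6-fold higher. Atg4d fell on its brightest probe alone (−2.01), while its 3 other probes rose by 2.95, 3.44 and 3.33. Membrane skeleton genes rose in 10 of 11 (median 2.49, 4.04e-05; adjusted p = 0.102 with an estimated correlation), among them Sptb, which rose on 2 of its 3 probes and fell on the other (−1.09). Ribosomal protein genes fell in 9 of 19 (median −0.88, camera adjusted p = 0.0034, and 0.0881 with an estimated correlation), with Rpl4 6.24-fold lower. With run as a block, medians were 3.66 for membrane skeleton, 3.205 for autophagy, 2.045 for haem and iron and −1.28 for ribosomal genes. Cell cycle genes rose in 9 of 25 (median 0.76, 0.0141), but their median lay 0.53 below that of all genes with median scaling or no normalization (−0.53), and adjusted p was 0.375 with an estimated correlation and 0.281 with run as a block (median 0.105). Erythroid transcription genes (4 of 11 higher, 4 lower; median 0.33, mean −0.92, 0.758) and stress genes (2 of 14 higher, 4 lower, Hspa1b on only 1 of its 2 probes; median −0.87, 0.937) did not pass. In limma, 6242 genes were called, 2701 higher and 3541 lower, against 8870 and 3200 with median scaling, 427 and 4543 without normalization between arrays, and 1570 and 2557 with run as a block. EryBlPO arrays detected 18.9% of probes and CFUE arrays 31.4%, and no run held both types.

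Megakaryocytes of the highest ploidy class (Meg32N, n = 3) were compared with those of the lowest (Meg8N, n = 3), all on the arrays of 1 run. Mest, an imprinted hydrolase gene, was 40.9-fold higher in Meg32N (11.62 ± 0.53 against 6.26 ± 0.33; log2 difference 5.36, SE 0.22, adjusted p = 3.84e-49), and Nyx, not well above background in Meg8N, at least 20.4-fold higher. Ctsk, cathepsin K, was lower (7.05 ± 0.94 against 12.56 ± 0.48, detected on 1 of 3 Meg32N arrays) as was Kit (6.10 ± 1.68 against 10.23 ± 0.075, also detected on 1 of 3). Cell cycle genes fell in 11 of 25 (12 adjusted over the list alone; median −1.15, adjusted p = 3.84e-07), among them the replication helicase genes Mcm4 by 3.35-fold and Mcm5 by 3.41-fold. Platelet protein genes rose in 10 of 19 (median 1.00, 1.98e-07) after quantile normalization, but their median was −1.61 without normalization and lay 0.37 below that of all genes with either other scaling (−0.37). Actin and cytoskeleton genes rose in 4 of 13 (median 0.74, 0.000136) after quantile normalization, but their median was −1.96 without it and −0.72 relative to all genes with either other scaling. The ADP receptor gene P2ry12 was 16.4-fold higher and the myosin light chain Myl9 9.89-fold higher, and neither was called without normalization. The neutrophil granule list did not pass (1 of 11 higher, the receptor gene Cxcr2, median 0.08, camera adjusted p = 0.68). Nor did erythroid genes (3 of 8 higher, median 0.95, 0.185). Stress genes did not pass either (4 of 14 higher, with 1 lower adjusted over the list alone, median −0.17, mean 0.12, 0.64). In limma, 2988 genes were called, 1442 higher and 1546 lower, against 9961 and 287 with median scaling, 13 and 7920 without normalization, and 1382 in all without background correction. Meg32N arrays detected 21.9% of probes and Meg8N arrays 34.8%.

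Pre-B cells (PreB, n = 3) were compared with pro-B cells (ProB, n = 3) across early B cell development. The DNA polymerase gene Polm was 43.8-fold higher in PreB (10.78 ± 0.48 against 5.33 ± 0.14), the adhesion gene Cd2 35.6-fold higher (10.44 ± 0.12 against 5.28 ± 0.23, detected on 2 of 3 ProB arrays) and the Ras activator Rasgrp1 35.1-fold higher. Dntt was 105-fold lower (5.74 ± 0.23 against 12.45 ± 0.33; log2 difference −6.71, SE 0.38, adjusted p = 7.67e-35), and Arpp21 75-fold lower. Il2ra, at least 21.1-fold higher, was part of the PreB gate. Antigen presentation and maturation genes rose in 9 of 13 (10 adjusted over the list alone; median 2.06, adjusted p = 4.88e-16), among them Ms4a1, which encodes CD20, by 10.7-fold and Cd40 by 10.1-fold. Pre-B receptor genes fell in 3 of 8, the surrogate light chain genes Igll1, Vpreb1 and Vpreb2 (with 1 higher adjusted over the list alone; median −0.19, 0.0255; adjusted p = 0.0695 with an estimated correlation), Igll1 by 11.1-fold. Cell cycle genes fell in 4 of 25 (10 adjusted over the list alone; median −0.83, 1.49e-06; adjusted p = 0.0543 with an estimated correlation), among them Tyms by 4.55-fold. Recombination genes (1 of 7 lower, Dntt; median 0.05, mean −0.77, adjusted p = 0.187), plasmacytoid dendritic cell genes (2 of 8 higher; median −0.01, mean 0.47, 0.306), T and NK cell genes (1 of 11 higher, 4 lower, 5 adjusted over the list alone; median −0.12, 0.471), myeloid genes (1 of 10 lower; median 0.05, mean −0.09, 0.866) and stress genes (2 of 14 higher, 3 adjusted over the list alone, and 1 lower; median 0.04, 0.319) did not pass. In limma, 1578 genes were called, 617 higher and 961 lower, with 949 in all without background correction and 732 without normalization. The count with a run block was 1733, with 1267 within run B (1 and 3 arrays).

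Peritoneal B1 and B2 cells (n = 2 each) were compared as the 2 B cell types of that cavity. Ctla4, an inhibitory receptor, was 9.06-fold higher in B1 (10.95 ± 0.06 against 7.76 ± 0.62; log2 difference 3.18, SE 0.35, adjusted p = 6.05e-13), and Wipf3, not well above background in B2, at least 5.14-fold higher. Fcer2a, which encodes CD23, was 57.9-fold lower (6.82 ± 0.12 against 12.68 ± 0.05), Vpreb3 60.7-fold lower (detected on 1 of 2 B1 arrays), and Satb1 17.5-fold lower. B1 cell genes rose in 5 of 12 (Ctla4, Zbtb32, Anxa2, Il10 and Fcrl5; median 0.96, adjusted p = 4.77e-11). Follicular B cell genes fell in 3 of 9 (Fcer2a, Cr2 and Bcl6; 5 adjusted over the list alone; median −1.03, 8.98e-10). Stress genes rose as a list (1 of 14 higher, Atf3 by 5.84-fold; median 1.01, 0.000196), but not with an estimated correlation (adjusted p = 0.176) or with run as a block (median −0.07, adjusted p = 0.828). Peritoneal macrophage genes (0 of 12; median 0.27, adjusted p = 0.174) fell with run as a block (median −0.49, adjusted p = 0.00151). Plasma cell genes (0 of 10; median 0.18, 0.459) and T and NK cell genes (1 of 11 higher, with 2 lower adjusted over the list alone; median −0.24, 0.204) did not pass. In limma, 313 genes were called, 185 higher and 128 lower, against 141 and 223 with median scaling, 143 and 22 without normalization, and 6 in all when these 4 arrays were fitted alone. With run as a block 337 were called, with 256 within run D (2 and 1 arrays), and without B1-2 162, 103 higher and 59 lower.

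Thymocytes at the third double-negative stage (TN3, n = 3) were compared with those of the stage before (TN2, n = 3), across which T cell identity is set. Cd3d, a chain of the T cell receptor complex, was 37.3-fold higher in TN3 (13.79 ± 0.21 against 8.56 ± 0.71; log2 difference 5.22, SE 0.41, adjusted p = 2.60e-23), and the pre-T receptor chain Ptcra 25.4-fold higher (10.07 ± 0.23 against 5.41 ± 0.09). Lef1, a transcription factor not well above background in TN2, was at least 22.1-fold higher. The haemoglobin gene Hbb-bs was 482-fold lower (5.62 ± 0.51 against 14.54 ± 0.04), myeloperoxidase, Mpo, 186-fold lower (detected on 2 of 3 TN3 arrays), and Lyl1, a stem cell transcription factor not well above background in TN3, at least 51.3-fold lower. T cell receptor genes rose in 7 of 9 (with 1 lower adjusted over the list alone; median 2.30, adjusted p = 1.09e-22), and T lineage and Notch genes rose in 5 of 10 and fell in Nrarp (median 0.87, 2.63e-08), among them Notch3 by 8.36-fold. Recombination genes rose in 2 of 7, Rag1 by 9.14-fold and Rag2 by 2.40-fold (median 0.67, 0.000886), the latter not called within run B (1 and 3 arrays). Progenitor genes fell in 9 of 11 (10 adjusted over the list alone; median −2.55, 9.36e-38), among them Hhex by 39.9-fold and Kit, a marker of the TN2 gate. Innate lymphocyte genes fell in 3 of 10, Fcer1g, Tyrobp and Cd244a, and rose in Id2 (median −0.44, 1.40e-06). Cell cycle genes (0 of 25; median −0.22, adjusted p = 0.197), B cell genes (0 of 6; median 0.10, 0.199) and stress genes (2 of 14 higher, 2 lower; median −0.24, 0.195) did not pass. In limma, 893 genes were called, 393 higher and 500 lower, against 391 and 766 with median scaling and 502 in all without background correction. Blocking on run gave 891, with 545 within run B (1 and 3 arrays).

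**Figure D2:**
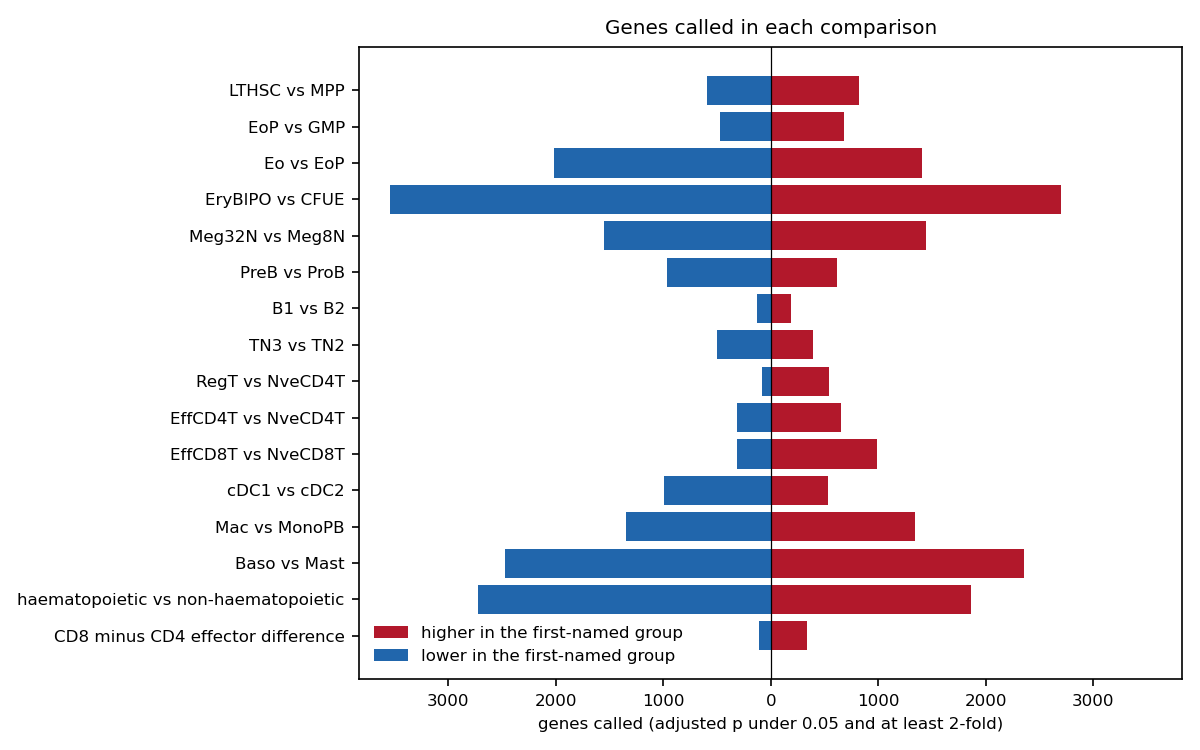
Number of genes called in each comparison by limma (adjusted p under 0.05 and at least 2-fold), with bars to the right for genes higher and to the left for genes lower in the first-named group. The highest count is 6242 genes for EryBlPO against CFUE and the smallest 313 for B1 against B2.

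Regulatory T cells (RegT, n = 3) were compared with naive CD4 T cells (NveCD4T, n = 4). Itgae, an integrin chain that binds epithelial cells, and the chemokine receptor Ccr6 were not well above background in NveCD4T and at least 42.3-fold and 25.9-fold higher in RegT. Ctla4 was 21.1-fold higher (11.01 ± 0.12 against 6.61 ± 0.31; log2 difference 4.4, SE 0.27, adjusted p = 9.69e-32, detected on 3 of 4 NveCD4T arrays) and the co-receptor gene Nrp1 35.8-fold higher. The largest falls were smaller, such as Tanc1 by 6.24-fold (5.71 ± 1.37 against 8.35 ± 0.47, detected on 1 of 3 RegT arrays), which was not called without RegT-1. Regulatory T cell genes rose in 16 of 18 and fell in 1, Foxp3 (median 3.06, adjusted p = 6.93e-85); Il2ra was part of the gate. The Foxp3 value rests on 1 probe, the brightest over all arrays (9.45 ± 0.24 against 10.75 ± 0.11). Its 3 other probes, which were brighter than that one in RegT (11.96, 10.94 and 9.95), were higher there by 5.27, 5.20 and 4.77 on the log2 scale. Cell cycle genes rose in 12 of 25 (13 adjusted over the list alone; median 1.01, 2.82e-23), among them survivin, Birc5, by 7.83-fold. Naive T cell genes fell as a list (1 of 10 lower, Dapl1 by 4.49-fold, 2 adjusted over the list alone, and 1 higher, Igf1r; median −0.42, 0.00623). Myeloid genes rose in 4 of 10, among them the lysozyme gene Lyz2 by 19.1-fold (detected on 3 of 4 NveCD4T arrays; median 0.94, 1.85e-09). B cell genes passed with 2 of 6 higher, Cd79b by 5.75-fold and Blk (median −0.03, mean 0.54, 0.0448; median 0.04 without normalization and −0.05 relative to all genes), but not with an estimated correlation (adjusted p = 0.0839). Stress genes did not pass (0 of 14; median 0.19, 0.632). In limma, 622 genes were called, 541 higher and 81 lower, against 350 and 3 without normalization and 274 in all without background correction. A block on run left 607, with 452 within run A (3 and 2 arrays), and without RegT-1 407, 399 higher and 8 lower.

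Effector CD4 T cells (EffCD4T, n = 3) were compared with the same naive cells (n = 4). Asb2, the chemokine receptor gene Cxcr3 and the cytokine gene Il4 were not well above background in naive cells and at least 173-fold, 148-fold and 87.5-fold higher in effector cells. Nkg7, a cytotoxic granule gene, was 133-fold higher (13.57 ± 0.24 against 6.52 ± 0.88; log2 difference 7.05, SE 0.36, adjusted p = 2.29e-40). Igfbp4, an insulin-like growth factor binding protein, was 38.4-fold lower (8.02 ± 0.69 against 13.29 ± 0.03), and Pdlim4 19.8-fold lower (8.03 ± 0.30 against 12.34 ± 0.26). Effector genes rose in 21 of 24 (median 3.5, adjusted p = 2.29e-87), among them Tbx21, the transcription factor T-bet, at least 38.7-fold, with Cd44 used in sorting. Helper subset genes rose in 8 of 10 (median 2.64, 5.21e-46), spanning Ifng, at least 22.5-fold, Il4, Il21 and Cxcr5. Inhibitory receptor genes rose in 4 of 8 (Lag3, Tigit, Ctla4 and Cd160, with a median of 1.88, 5.99e-14), Cd160 by 71.5-fold. Of the Foxp3 probes 3 were higher in EffCD4T than in naive cells (9.28 against 6.69, 8.11 against 5.74 and 7.16 against 5.18). The probe brightest over all arrays was lower (8.76 against 10.75). Ctla4 and Itgae (higher here by 4.00 on the log2 scale) were also higher in RegT. Whether regulatory T cells were among the effector cells was not tested. Naive T cell genes fell in 4 of 10 (5 adjusted over the list alone; median −0.89, 1.07e-09), among them the actin crosslinker Actn1 by 4.77-fold. B cell genes (0 of 6; median 0.10, adjusted p = 0.418), myeloid genes (1 of 10 higher, Lyz1, not called without NveCD4T-4, with 1 lower adjusted over the list alone; median 0.01, 0.481) and stress genes (1 of 14 higher; median 0.13, 0.546) did not pass. In limma, 972 genes were called, 658 higher and 314 lower, against 409 and 110 without normalization and 502 in all without background correction. With run as a block 977 were called, with 586 within run A (1 and 2 arrays) and 520 within run B (2 and 1 arrays).

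Effector CD8 T cells (EffCD8T, n = 3) were compared with naive CD8 T cells (NveCD8T, n = 3), all in 1 run. The chemokine genes Ccl3 and Ccl9 and the cytokine gene Il4 were not well above background in naive cells and at least 66.1-fold, 58.0-fold and 49.3-fold higher in effector cells. Ccl4 was 70.0-fold higher (12.71 ± 0.31 against 6.58 ± 0.33; log2 difference 6.13, SE 0.66, adjusted p = 2.04e-14). Some genes of other cell types, named for the interaction below, were also higher on the effector arrays. On the log2 scale these were the basophil genes Prss34 (5.498) and Mcpt8 (4.92), Ear3 of eosinophils (4.999) and Slc4a1 of red cells (5.63). Ccl3, Ccl4 and Il4 also belong to the basophil list used below, which was not tested here. Whether RNA of other cells contributed to these rises was not tested. Ampd1, a muscle-type AMP deaminase, was 23.2-fold lower (6.04 ± 0.51 against 10.57 ± 0.02) and the amino acid transporter Slc6a19 20-fold lower (5.53 ± 0.21 against 9.85 ± 0.13). Effector genes rose in 18 of 24 (median 3.98, adjusted p = 3.95e-51), among them Klrk1, an activating receptor, at least 25.3-fold, and Tbx21 by 17.3-fold. Cell cycle genes rose in 18 of 25 (19 adjusted over the list alone; median 1.98, 1.60e-19), among them Nusap1 by 11-fold, and inhibitory receptor genes in 6 of 8 (median 2.08, 2.77e-13), Ctla4 by 34.0-fold. Naive T cell genes fell in 4 of 10 (median −0.80, 0.000736), among them Lef1 by 3.95-fold. Myeloid genes rose in 6 of 10 (median 2.10, 9.95e-09), among them Lyz2 by 18.1-fold (11.19 ± 0.41 against 7.00 ± 0.74). B cell genes (1 of 6 higher, Blk at least 13.2-fold, and 1 lower, Cd79b; median −0.07, mean 0.50, adjusted p = 0.308) and stress genes (0 of 14; median 0.46, 0.455) did not pass. In limma, 1304 genes were called, 990 higher and 314 lower, against 1450 and 157 with median scaling, 1165 and 82 without normalization, 705 in all without background correction and 1421 with run as a block.

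The effector difference itself was tested between the CD8 and CD4 cells. Nkg7 showed the largest gap, at 7.05 in CD4 and −0.11 in CD8 cells (interaction −7.16, SE 0.52, limma adjusted p = 1.56e-24), followed among the falls by Itgae (4.00 and −1.10) and Plac8 (4.76 and −0.26). The largest interactions the other way were those of Prss34, a basophil protease (5.76, SE 1.12), and Ear3, an eosinophil ribonuclease (5.73, SE 1.44), and that of the red cell anion exchanger Slc4a1 was 4.98. Alox5ap, which serves leukotriene synthesis, had this pattern as well, at −0.16 in CD4 and 5.12 in CD8 cells (interaction 5.28, SE 0.50), as did Ccl9 (1.05 and 6.14), the water channel Aqp1 (0.54 and 5.59), and the basophil protease gene Mcpt8 (−0.08 and 4.92). Cxcr6 rose in both, by 6.66 and 2.13, with an interaction of −4.53. Myeloid genes, whose list was tested here only after its values in each subset were seen, had a higher CD8 difference in 4 of 10 (median 2.11, unadjusted camera p = 2.75e-12, and 6.23e-05 with an estimated correlation). Genes of other cell types therefore moved with this difference. In all, 444 genes were called, 336 with a higher CD8 difference and 108 with a lower one, against 479 and 71 with median scaling, 292 and 29 without normalization, 509 in all with run as a block and 197 within run B (3 and 3 CD8 arrays, 2 and 1 CD4 arrays).

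The 2 conventional dendritic cell types of lymph node (cDC1 and cDC2, n = 3 each, all in 1 run) were compared. Xcr1, the chemokine receptor of cDC1, and Cd207, langerin, were not well above background in cDC2 and at least 41.5-fold and 57.0-fold higher in cDC1. Notch4 was 44.8-fold higher (12.68 ± 0.11 against 7.20 ± 0.25; log2 difference 5.48, SE 0.38, adjusted p = 1.25e-27). The lectin gene Cd209a and Tlr7, a sensor of RNA, were not well above background in cDC1 and at least 44.9-fold and 19.4-fold lower there, and Sirpb1a was lower (5.26 ± 0.83 against 12.39 ± 0.12, detected on 1 of 3 cDC1 arrays). cDC1 genes rose in 9 of 15 (11 adjusted over the list alone; median 2.71, adjusted p = 1.17e-34), among them Tlr11 by 9.68-fold, and cDC2 genes fell in 9 of 13 (median −3.86, 7.85e-21), among them Mgl2 by 44.1-fold. Plasmacytoid dendritic cell genes fell in 7 of 8 (median −3.99, 7.26e-19), Klk1 by 55.3-fold (detected on 2 of 3 cDC1 arrays), and T and NK cell genes in 8 of 11 (median −1.54, 2.62e-12), Nkg7 by 23.9-fold (7.09 ± 0.26 against 11.67 ± 0.39). Maturation genes fell in 4 of 12, Ccl17 by 7.52-fold, and rose in Cd86 by 3.48-fold (median −0.28, 0.0476; adjusted p = 0.076 with an estimated correlation and 0.0544 with run as a block). Class II presentation (0 of 8; median −0.07, mean 0.06, adjusted p = 0.719), B cell genes (1 of 6 lower, Cd79b by 8.33-fold; median −0.21, 0.11) and stress genes (0 of 14; median −0.18, 0.805) did not pass. In limma, 1525 genes were called, 534 higher and 991 lower, against 123 and 735 without normalization, 889 in all without background correction and 1612 with run as a block.

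Peritoneal macrophages (Mac, n = 5) were compared with blood monocytes (MonoPB, n = 3). Vsig4, a complement receptor, Retnla, a resistin-like factor, and the B cell chemokine Cxcl13 were not well above background in monocytes and at least 363-fold, 356-fold and 227-fold higher in macrophages. C4b, a complement component, was 206-fold higher (13.52 ± 0.56 against 5.83 ± 0.33; log2 difference 7.69, SE 0.39, adjusted p = 2.26e-40). Ltf and the granule protein gene Ngp, not well above background in macrophages, were at least 186-fold and 176-fold lower, and Elane, neutrophil elastase, was lower (5.68 ± 0.63 against 13.74 ± 0.16, detected on 2 of 5 macrophage arrays). Complement genes rose in 7 of 8 (median 4.72, adjusted p = 1.12e-17), C1qa by 129-fold, and lipid handling genes rose in 5 of 12 and fell in Scarb1 (median 0.74, 0.000252), Apoe by 13.6-fold. All 11 genes of the secondary neutrophil granule list fell (median −5.92, camera adjusted p = 4.88e-16). Stress genes rose in 9 of 14 (11, with 1 lower, adjusted over the list alone), Egr1 by 31.3-fold. Their median was 2.27 (camera adjusted p = 0.000122, and 0.163 with an estimated correlation). It was 1.22 with run as a block (camera adjusted p = 0.0318) and 1.07 within run A (3 and 1 arrays). Mast cell proteases, examined after their levels were seen, were not well above background in monocytes but stood at 10.81 ± 0.69 (Cma1), 10.59 ± 0.92 (Mcpt4) and 8.98 ± 0.37 (Tpsb2) in macrophages. Class II genes (3 of 8 higher, among them H2-Ab1 by 4.59-fold; median 0.79, adjusted p = 0.327) passed only with run as a block (adjusted p = 0.0113). Lysosome genes (5 of 14 higher, with 1 lower adjusted over the list alone; median 0.45, 0.154), T and NK cell genes (1 of 11 higher, 2 lower; median −0.16, 0.263) and B cell genes (2 of 6 higher; median 0.13, 0.449) did not pass. In limma, 2686 genes were called, 1340 higher and 1346 lower, against 1753 and 1150 with median scaling, 647 and 1220 without normalization, and 1638 in all without background correction. The number with run as a block was 2592, with 1695 within run A (3 and 1 arrays).

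Basophils of spleen (Baso, n = 2) were compared with peritoneal mast cells (Mast, n = 2). Mcpt4, Cma1 and Tpsb2, which encode mast cell chymases and a tryptase, were not well above background in basophils and at least 164-fold, 154-fold and 147-fold lower there. Ccl3, Ccl4 and Grm6 were not well above background in mast cells and at least 324-fold, 337-fold and 109-fold higher in basophils. The water and glycerol channel Aqp9 was 250-fold higher (14 ± 0.10 against 6.04 ± 0.80; log2 difference 7.96, SE 0.41, adjusted p = 4.43e-40, detected on 1 of 2 mast cell arrays). Mast cell proteases and receptors fell in 9 of 11 (median −9.12, adjusted p = 9.44e-21). Basophil genes rose in 8 of 11 (median 3.00, 3.20e-06), among them the integrin Itga2 by 13.4-fold (detected on 1 of 2 mast cell arrays), not called without normalization. Peritoneal macrophage genes fell in 10 of 12 (11 adjusted over the list alone; median −4.18, 8.99e-12), with Vsig4 at 10.79 ± 1.62 in mast cells and not well above background in basophils. T and NK cell genes rose in 7 of 11 (8 adjusted over the list alone; median 3.57, 4.68e-07), with Cd3d at 10.51 ± 0.87 in basophils and not well above background in mast cells. With run as a block, resting on other types, the list still passed (median 2.12, adjusted p = 0.00291), but only Zap70 of the 7 was still called. Differences mostly fell and standard errors about doubled: Cd3d went from 5.195 (SE 0.50) to 3.16 (SE 1.17) and Thy1 from 5.87 (SE 0.48) to 2.12 (SE 1.01). The list of shared IgE receptor genes did not pass (1 of 7 higher, median −0.22, mean 0.53, camera adjusted p = 0.455). Its median was 0.92 under median scaling and 0.96 with run as a block. The 1 was Csf2rb, a cytokine receptor chain, at least 31.5-fold. B cell genes (0 of 6, median 0.18, 0.876, but −1.035 with run as a block) did not pass. Nor did stress genes (5 of 14 higher, 1 lower, median 0.76, 0.0584). In limma, 4822 genes were called, 2356 higher and 2466 lower, against 1014 and 3651 with median scaling, 160 and 11144 without normalization, and 658 and 871 with run as a block, which rests on other types because no run held both.

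**Figure D3:**
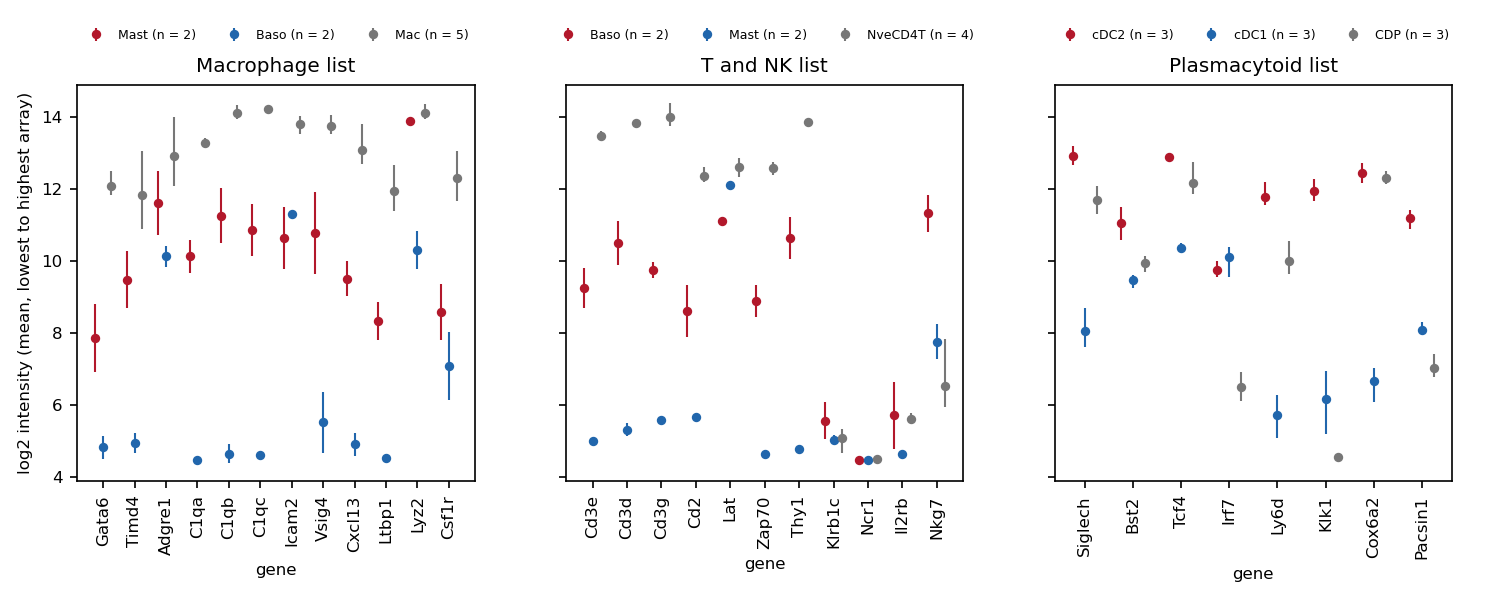
Log2 intensity (vertical axis) of genes of 3 lists in the arrays where they stood out and in types for comparison, with points for means and bars from the lowest to the highest array. Macrophage genes such as Vsig4 reach 10.79 on mast cell arrays, and T cell genes such as Cd3d reach 10.51 on basophil arrays.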

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

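The tests of macrophage, T cell and NK cell RNA, of T cell and plasmacytoid cell RNA on cDC2 arrays, and of runs were chosen after the patterns were seen; the tests of quantile normalization were written beforehand. The shares of a source's bright genes raised on every array decided nothing about RNA from other cells, and the test of the CD3 genes was added after those shares were known.

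Mast cell arrays carried macrophage genes, 10 of 12 of which were lower in basophils. The median of −3.81 with median scaling, relative to all genes, argues against quantile normalization. With run as a block the median was −3.27 and 8 of the 10 stayed called, while Lyz2 went from −3.58 to 0.69. That block rests on other types, since no run held both mast cells and basophils, so a difference between runs stays open. RNA of peritoneal macrophages stays open. Of 116 genes bright in macrophages, 75.86% were raised on both arrays, against a median of 17.2% in other types. On NeutLN arrays 77.6% were raised, but 3 of 5 macrophage markers were also higher there than in peritoneal neutrophils, so they are no clear comparison. Mast cell genes were in turn raised on the macrophage arrays, 57.9% of 107 genes bright in mast cells against a median of 18.7% and at most 52.3% (NeutLN) in other types, with Cma1 at 10.81 and Mcpt4 at 10.59, so each of these 2 peritoneal types carried genes of the other. The mast cell gate excluded the macrophage antigens F4/80 and Mac-1, and expression by the mast cells themselves may account for it as well and was not tested.

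Basophil arrays carried T and NK cell genes, 7 of 11 of which were higher than in mast cells. The median was 2.45 with median scaling, relative to all genes, which argues against quantile normalization. NK cell RNA is argued against as the source of the CD3 genes Cd3d, Cd3e and Cd3g. These stood at 50.8% to 68.0% of their NK level, at least 32.4% between single arrays, and only 38.46% of the 65 genes bright in NK cells could reach that lowest share on any array. For the rest of the list NK cell RNA stays open, with 69.23% of the bright genes raised. T cell RNA stays open, with 77.14% of 35 bright genes raised. The share was 85.7% on NeutLN arrays, where 3 of 4 T cell markers were also higher than in peritoneal neutrophils. Of 32 genes, 96.88% could reach the share the CD3 genes would need, but 37.5% did so by the strictest reading. The basophil gate names no exclusion of T cells. A difference between runs stays open too, since the median was 2.116 with run as a block but only 1 of the 7 genes was still called. Expression by basophils may also account for part of it and was not tested.

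On the cDC2 arrays 7 of 8 plasmacytoid dendritic cell genes were higher than on cDC1 arrays. Quantile normalization is argued against by a median of −4.41 with median scaling, relative to all genes. T cell RNA cannot supply these genes, whose median level lay 5.80 above that of naive T cells on the log2 scale. Whether T cell RNA is present stays open, since 8 of 11 T and NK cell genes were also higher in cDC2 and 64.7% of genes bright in T cells were raised. That share had a median of 17.65% in other types but reached 88.2% on NeutLN arrays. RNA of plasmacytoid cells may contribute and cannot be told apart from expression by cDC2, since no array holds such cells and the gate names no marker of them. The share of the list's genes lower in cDC1, 87.5%, only restates the pattern and decides nothing.

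Single arrays stood apart from the rest of their group in 16 of 188 pairs of a gene and a group, where chance gives about 9.4, a value that takes no account of run. LTHSC-1 was the only LTHSC array of run D, GMP-1 the only GMP array of run A and NveCD4T-4 the only naive CD4 array of run P, so run cannot be told apart from the array there. LTHSC-1 had Irf8 at 7.32 (others 4.88 to 5.26), Il12a at 8.92 (9.72 to 9.84), Kif11 at 7.97 (8.86 to 9.01) and Epor at 8.00 (9.04 to 9.23). MPP-5 had Epor at 6.74 (5.07 to 5.54). GMP-1 had Ccne2 at 9.72 (7.76 to 8.50), Alox15 at 5.01 (4.51 to 4.64) and Irf8 at 10.23 (10.84 to 11.20), and detected 39.2% of probes, within the 32.5% to 43.8% of run A arrays, against 28.7% to 32.8% on the other GMP arrays. GMP-2 had Crhbp at 4.81 (4.46 to 4.58) and GMP-3 Cxcr2 at 5.98 (6.65 to 7.11). NveCD4T-4 had Nkg7 at 7.84 (5.95 to 6.16) and Tmem108 at 7.99 (9.38 to 9.41), and NveCD4T-2 had Fcgr3 at 6.64 (6.33 to 6.36). Mac-2 had C4a at 13.97 (14.42 to 14.55), Mac-1 Prg2 at 6.24 (4.47 to 4.75) and Mac-3 Mpo at 8.29 (4.45 to 4.86). The effector difference of 444 genes differed between CD8 and CD4 T cells by the test of the difference itself (197 within run B), myeloid, basophil and eosinophil genes among them. Whether RNA of such cells in the effector CD8 samples accounts for those genes was not tested.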

How the results depend on the processing

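The settings named here as run, within run, median scaling, no normalization and arrays under 25% were chosen after seeing the data. Most values of named genes kept their direction and side of the threshold. Outside the runs with an array left out 6774 were the same, 61 stronger, 240 weaker and 44 reversed. With an array left out 16674 were the same, 26 stronger, 172 weaker and 0 reversed. Most of these genes were named for large differences or small adjusted p, so this says little of the results as a whole. For Meg32N the share of called genes that were higher went from 48.3% to 97.2% with median scaling and 0.164% without normalization. The cause of the changes below was not tested, except where fewer arrays or a stricter rule entered. Chips are not named, so a chip block was not run. Without background correction the counts given next all fell.

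Without background correction the counts were 666 for LTHSC, 495 for EoP, 2082 for Eo, 1382 for Meg32N, 949 for PreB, 502 for TN3, 274 for RegT, 502 for EffCD4T, 705 for EffCD8T, 889 for cDC1, 1638 for Mac and 2616 for blood, and 114, 77, 49, 39, 187, 0 and 24 for the lineages of basophils, dendritic cells, macrophages, multipotent progenitors, NK cells, restricted progenitors and T cells. With adjusted p alone they were 2715 for LTHSC, 1923 for EoP, 4539 for Meg32N and 13296 for blood. With only the arrays compared B1 had 6. With every type above every other, lineages had 5 genes (B), 78 (basophil), 0 (dendritic), 6 (eosinophil), 13 (erythroid), 8 (macrophage), 174 (mast), 46 (megakaryocyte), 3 (multipotent), 77 (NK), 121 (neutrophil), 0 (restricted) and 1 (T).

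With run as a fixed block Eo had 1342, EryBlPO 4127 and Baso 1529, and within runs LTHSC 633 (D), TN3 545 (B), EffCD4T 586 (A) and 520 (B), Mac 1695 (A) and the interaction 197 (B). Without normalization EoP had 364, Meg32N 7933, PreB 732, B1 165, RegT 353, EffCD4T 519, cDC1 858 and Baso 11304, and lineages 162 (B), 17 (basophil), 98 (erythroid), 117 (macrophage), 1574 (mast), 58 (megakaryocyte), 51 (multipotent), 26 (NK) and 121 (T). With median scaling EryBlPO had 12070 and Meg32N 10248, and lineages 96 (basophil), 67 (dendritic), 159 (erythroid), 946 (mast), 60 (multipotent), 190 (NK) and 1 (restricted). Without arrays under 25% the erythroid lineage had 166 (3 of its 6 types left) and restricted progenitors 1. After quantile normalization the median difference of all genes was −0.11 for Eo and within 0.05 of 0 for the other comparisons. It was, with median scaling, 0.55 for LTHSC, 0.44 for EoP, −0.44 for Eo, 1.26 for EryBlPO, 2.06 for Meg32N, −0.36 for B1, 0.11 for cDC1, 0.53 for Mac, 0.14 for Baso and −0.53 for blood, and without normalization −0.53 for LTHSC, −0.27 for EoP, 0.77 for Eo, −1.24 for Meg32N, 0.37 for B1, 0.12 for TN3, −0.15 for cDC1, −1.64 for Baso, 0.24 for blood and 0.16 for the interaction.

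Leaving out 1 array at a time (100 arrays for the broad results, 85 for the others; a lone array left in a group is assumed to vary like the other groups) gave 1179 to 2090 for LTHSC, 938 to 1240 for EoP, 2961 to 3660 for Eo, 5925 to 6789 for EryBlPO, 2734 to 3375 for Meg32N, 1337 to 1693 for PreB, 162 to 338 for B1, 768 to 841 for TN3, 407 to 888 for RegT, 880 to 1035 for EffCD4T, 1022 to 1290 for EffCD8T, 318 to 444 for the interaction, 1379 to 1474 for cDC1, 2353 to 2894 for Mac, 3944 to 4847 for Baso and 4550 to 4597 for blood. For lineages it gave 86 to 92 (B), 179 to 325 (basophil, the highest without Baso-2), 113 to 118 (dendritic), 43 to 51 (eosinophil), 300 to 325 (erythroid), 66 to 79 (macrophage), 427 to 509 (mast), 236 to 259 (megakaryocyte), 85 to 98 (multipotent), 248 to 488 (NK, the highest without NK-2), 352 to 400 (neutrophil), 1 to 2 (restricted; 1 without LTHSC-1, CD9Hi-3 or Mast-2) and 36 to 41 (T).

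With the replicate number as a block LTHSC had 1544, EoP 1348, Eo 3440, EryBlPO 6253, Meg32N 3009, PreB 1596, B1 320, TN3 904, RegT 675, EffCD4T 950, EffCD8T 1316, cDC1 1534, Mac 2662, Baso 4856, blood 4592 and the interaction 449. Outside cDC1 and cDC2 same-numbered arrays did not deviate together in every pair. Their mean correlation was 0.413 for PreB, 0.271 for TN3, 0.216 for EffCD4T and 0.205 for RegT, and at most 0.085 for the other comparisons. Arrays deviated most with their own number in 2 of 3 cases for Meg32N, PreB, RegT and EffCD4T and 1 of 3 for EoP, EryBlPO, TN3 and Mac. It was 0 for LTHSC, Eo and EffCD8T, and 2 of 2 for Baso (correlation 0.085). The block changed 2 list calls, of mast cell genes in LTHSC (adjusted p = 0.0303) and B cell genes in RegT (0.0527). B1 and B2 pairs correlated at −0.10, and crossed pairing gave 318 calls, 187 higher and 131 lower.

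Directions reversed in these cases. With every type above every other the smallest differences were −0.52 for Blk, −0.70 for Ms4a1, −5.28 for Adam23, −3.40 for Ffar4, −2.24 for Arhgap22, −2.99 for Zbtb46, −1.34 for Xcr1, −3.53 for Ccr7, −0.16 for Clec9a, −0.39 for Klf1, −0.48 for Csf1r, −0.79 for F13a1, −1.95 for Gm5111, −0.66 for Cadps2, −0.54 for Eomes, −0.055 for Retnlg, −2.58 for Cdk6, −2.67 for Gm2629, −5.39 for Trbv13-1, −1.95 for Camk4, −1.96 for Slc16a5, −4.98 for Cd3e, −4.38 for Cd3g and −3.68 for Bcl11b. Without normalization Meg32N had −0.41 for Cxcr2, −0.63 for Gp6, −0.87 for Clec1b, −1.82 for Tpm1, −1.73 for Flna, −1.86 for Epor, −0.33 for Alas2, −0.54 for Rhag, −0.85 for Zfp36, −0.57 for Atf3 and −1.65 for Junb, Baso had −1.31 for Fcer2a, and the lineage values were −0.35 for Il4 in basophils and −0.34 for Ncr1 in NK cells. Rpl4 in Eo was 0.30 without normalization and 0.80 with the mean of all probes. With run as a block Ier3 in EryBlPO was −0.011 and Junb in Baso −0.36, with median scaling Pax5 in B cells −0.53, and within run G Prss34 in LTHSC 0.29.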

Other observations

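The 8 restricted progenitor types were each compared with the mean of the other 7, with genes chosen after their values were seen and no list tested. Run was not taken into account: all CLP arrays were of run Q, which held none of the other 7 types, CMP arrays were of run H with 3 of the 7 GMP arrays, and the other 5 types of run N. Common lymphoid progenitors (CLP) differed most, with 1155 genes higher and 1278 lower: Dntt was higher by 7.77 on the log2 scale (SE 0.29, limma adjusted p = 1.92e-55), the interleukin receptor Il7r by 6.48 and Ly6d by 8.26, and the stem and progenitor factor Gata2 fell by 6.85. The CD9Hi cells (359 higher, 326 lower) had platelet genes, with Pf4 higher by 5.06, Vwf by 4.9 and Gp1bb by 4.03. BEMP cells (306 higher, 475 lower) had the erythroid genes Klf1 (3.60) and Car1 (3.86), with Irf8 lower (−4.02). FcgRBP cells (455 higher, 109 lower) had neutrophil granule genes, with Ngp higher by 6.33 and Ltf by 6.08, but not these alone. The markers listed beforehand were higher there for neutrophils (4 of 5, median 2.21), basophils (5 of 5, 2.38) and megakaryocytes (5 of 5, 2.57). Those of erythroid cells (3 of 4, median 1.85) and eosinophils (3 of 6, 1.9) were higher as well. GMP (483 higher, 634 lower) had Ms4a3 (3.80) and Fcgr3 (4.03), CMP (377 higher, 243 lower) Vwf (2.70, less than in CD9Hi), PreGM1 (153 higher, 246 lower) Dntt (2.50, less than in CLP), and PreGM2 (104 higher, 49 lower) Elane (2.61).

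Lymph node cells were set against their counterparts from elsewhere, also with genes chosen after their values were seen. No run held both the lymph node and the other monocytes, or both kinds of neutrophil, so run cannot be separated from source there. Lymph node monocytes against blood monocytes (938 genes higher, 810 lower) had the stress genes Fosb (7.70), Hspa1a (7.62) and Egr1 (7.13) higher, together with Glycam1 (6.96), a gene of lymph node vessels. Neutrophils of lymph node against those of peritoneum (1843 higher, 671 lower) also had Glycam1 higher (8.08), with the stromal chemokine Ccl21a (6.58) and Ccl5 (6.52). Their T cell (3 of 4, median 4.71), mast cell (3 of 5, 2.93), dendritic (4 of 6, 1.86) and macrophage markers (3 of 5, 1.36) were higher. Eosinophil markers were lower in 3 of 6. Lymph node monocytes likewise had T cell (3 of 4, median 2.64) and dendritic markers (4 of 6, 1.555) higher. Markers lower there included those of neutrophils (3 of 5), basophils (4 of 5, median −1.43) and eosinophils (3 of 6, −2.92). The largest falls were those of the eosinophil granule gene Prg2 (−7.28) and the basophil protease gene Prss34 (−6.885). The blood monocyte arrays, which were also compared with Mac, thus had more signal of these genes. Migratory dendritic cells against cDC2 (975 higher, 988 lower) had Cd207 higher (5.03) and Cd209a lower (−6.0). Genes of the sex chromosomes differed as well, and the labels do not give the sex: the difference of the Y chromosome gene Eif2s3y was −7.11 for neutrophils (4.57 against 11.68, with Xist at 9.98 against 4.47) and −5.42 for monocytes. Among the comparisons of the report Eif2s3y was called higher in Eo (2.84), Kdm5d lower in EryBlPO (−1.64), and Xist (1.69), Eif2s3y (1.96) and Kdm5d (1.09) higher in blood cells. Neutrophil granule genes were high on monocyte arrays of blood (Elane 13.74, Ltf 13.46), where 79.1% of 158 genes bright in neutrophils were raised against a median of 18.0% and at most 84.8% (Eo) in other types, and on eosinophil arrays (Ltf 14.03).

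A hypothesis formed from these data, whose test was written before its result was seen, held that LTHSC carry genes of megakaryocytes. Over the 247 megakaryocyte-enriched genes the median difference from MPP was 0.40, with 79 called higher and 8 lower, and camera with an estimated correlation gave an adjusted p of 2.932e-05 over 13 lineage gene sets. The idea and the 247 genes both came from these arrays, LTHSC and MPP among them, so this p-value is no independent support. The multipotent (median 0.97, camera adjusted p = 0.00527) and erythroid sets (0.19, 0.0417) were also higher. The shift may therefore not be special to megakaryocytes.

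Other splits of the same samples were fitted to ask whether a random grouping gives as many genes. No other split that was fitted reached the real count for LTHSC against MPP (1409, highest other 1400, 100 of 210 possible splits). Nor did any for EoP against GMP (1151, highest other 620, 100 of 120) or Mac against MonoPB (2686, 2244, all 56). The same held for RegT (622, 417, all 35) and EffCD4T against NveCD4T (972, 670, all 35). The real grouping thus gave more genes than every other split fitted. These splits take no account of run, and not all were fitted for LTHSC and EoP, so they cannot exclude chance. For blood against other sources, redrawn sets of 8 cell types gave at most 1890 (real count 4585, 100 sets with the real one). Such sets mix unlike types, so they do not bear on chance. The closest split of the stem cells grouped MPP-1, MPP-2 and MPP-3, which are run D, with MPP-5 and gave almost the real count, so the stem cell count alone does not set the types apart from runs; it was 1313 within run G and 633 within run D. The closest split of Mac grouped Mac-4 and Mac-5 of run J. Designs with 10 splits cannot give a share under 0.05: the real and highest other counts were 3428 and 540 for Eo, 6242 and 3219 for EryBlPO, 2988 and 622 for Meg32N, 1578 and 178 for PreB, 893 and 35 for TN3, 1304 and 56 for EffCD8T and 1525 and 81 for cDC1. For the interaction no other of 100 splits, from 700 possible, reached the real count (444, highest other 178). These splits take no account of run either. The effector effect that CD4 and CD8 cells share was taken out before these splits. A first count left it in and did not exclude chance, but it was void, since regrouping turned that shared effect into differences between the subsets. For lineages, sets of as many blood cell types were redrawn at random. These mix unlike types, so they do not bear on whether a lineage's genes arose by chance. Of 100 sets, only the real one reached the real count for B cells (90, highest other 36) and erythroid cells (320, 36). The same held for megakaryocytes (247, 110) and T cells (39, 3). For dendritic cells (117, 174) and multipotent progenitors (94, 174) 2 of 100 did, the real one among them. It was 27 of 100 for eosinophils (46, up to 669) and 12 for restricted progenitors (2, up to 10). For neutrophils (389, up to 669) it was 8 and for macrophages (76, up to 110) 5. In each of these lineages the highest other set held Retic, whose arrays detected 6.18% of probes on average. These split counts were chosen after the results were seen.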
